A study of Mus musculus with 6 samples.

How the data were processed

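Colon tissue of STAT6-/- and WT BALB/c mice given 3% DSS for 3 days was profiled by RNA sequencing, with 3 samples per genotype and 1 library per sample. Per the labels' protocols, proximal intestine was taken, rinsed and scraped on its luminal side, pieces of colon were made, and total RNA was extracted with Trizol. The labels do not state whether the 3 replicates of a genotype are separate animals, so the p-values measure the spread between samples, which may be partly technical.

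The expected counts, deposited by the authors as 1 table per library, are estimated read numbers per RefSeq transcript without normalization between libraries, per the file headers. The FPKM values beside them were scaled by the authors to transcript length and mapped fragments, per the file headers. Bowtie2 2.2.5, RSEM 1.2.12 and the mouse build mm10 are named in the submitters' processing notes. Only transcripts with an FPKM of 0.01 or more are listed, and a transcript missing from a library was taken as 0.

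Expected counts were summed over the transcripts of each gene and rounded to whole numbers. Of 28238 transcripts, 27986 took their gene from a RefSeq gene table of GRCm38.p6, the assembly of mm10, and 129 from GENCODE M21. The other 123, with 0.196% of the counts, had no gene name and were each kept as a separate entry. This gave 19951 genes, these entries included. Coordinates are those of mm10. The libraries held 17122315 to 19555450 expected counts. A gene absent from a library was given an upper limit of 3 counts, which is 0.153 to 0.175 CPM before TMM scaling. Folds called "at least" use that limit after TMM scaling, as a mean over the WT libraries.

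Genotypes were compared with edgeR 4.0.16 (R 4.3.3) by its quasi-likelihood F test with TMM factors, the filterByExpr filter and robust estimation. A gene passed at a Benjamini-Hochberg adjusted p below 0.05 over the 15066 tested genes, and "rose" and "fell" are used for genes that passed. Unless another test is named, every adjusted p of a gene is from edgeR. CPM are means ± SD of 3 libraries, and the SE of a log2 fold change is its size over the square root of the F statistic. The common dispersion was 0.102. An exact permutation test was added for Stat6. Genes named by size were those with a mean log2 CPM of at least 1 and no overlap between the groups: the 10 with the largest rise and the 10 with the largest fall.

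The lists of genes were fixed, with the tests and the rule for naming genes, before the data were examined. All 40 lists are described in the report. They were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the 39 lists with at least 4 tested genes. The same test with an estimated correlation called 0 lists, with adjusted p from 0.417 to 0.983 and 1 list at an unadjusted p under 0.05. For each list the text names up to 4 genes with the smallest p and the most abundant one. Other members, named where 5 or fewer changed or to give a range, were chosen after their values were seen. So was the choice to name every changed clock gene. Some genes that this rule selects are not reported here. Genes within 10 Mb of Stat6 were compared with all others by Fisher's exact test.

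The gene test was tested on simulated data with 200 of 14878 genes changed. It recovered 14% of the 2-fold and 78% of the 4-fold changes, with 4 false calls among 96, so that small changes were often missed there with 3 libraries a group. In the data a far larger share of genes was called, 22.9%. Recovery depends on that share, so the simulated percentages may not hold for the data. In a simulation with 1 list raised 2-fold, camera called that list and 0 others. The simulated genes varied independently of one another, so this does not show how often camera calls lists falsely when genes are correlated.

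Alternatives were other scalings (RLE, library size, upper quartile), no filter or a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, no robust estimation, limma on log2 FPKM with 1 or 0.1 added, a replicate block, genes over 1% of a library left out, and each library left out in turn. A fit that removed trends on GC content and transcript length was added after the data were seen. Figures were drawn with matplotlib 3.10.9.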

Results

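The series measured colon mRNA in BALB/c mice that carry a disrupted Stat6 gene (STAT6-/-) and in wild-type (WT) mice of the same labelled strain. STAT6 is the transcription factor that relays interleukin-4 and interleukin-13 signals. Mice aged 6 to 8 weeks drank 3% dextran sulfate sodium (DSS), a compound that injures the colonic epithelium, for 3 days before the tissue was taken. Each genotype had 3 libraries. The STAT6-/- libraries held 19555450, 19224779 and 19522272 expected counts and the WT libraries 17137595, 17433876 and 17122315. The most abundant gene in all 6 libraries was Lypd8, an epithelial protein that keeps flagellated bacteria off the colonic surface, with 1.31% to 2.48% of the counts. The comparison asked which transcripts differ between STAT6-/- and WT colons under DSS, and colons without DSS are not analysed here.

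Stat6 itself (chromosome 10, 127642955 to 127660987, mm10) was 2.01-fold lower in the STAT6-/- colons. It stood at 47.2 ± 7.74 CPM (counts scaled to library size with TMM factors, mean ± SD, n = 3) against 94.8 ± 8.11 in WT. The log2 fold change was -1.01 ± 0.17 (SE; edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0134), and all 3 STAT6-/- libraries lay below all 3 WT libraries. An exact two-sided permutation test gave p = 0.1, the smallest that 3 libraries against 3 can give. The STAT6-/- colons thus held 49.8% of the WT level, and counts summed over whole transcripts do not show which part of the gene was disrupted. The edgeR adjusted p was 0.0725 without WT replicate 2 and 0.0721 without WT replicate 3.

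The sex-linked genes split exactly by genotype. Xist, the RNA that silences an X chromosome in females, stood at 469 ± 103 CPM in WT and 0.683 ± 0.376 CPM in the STAT6-/- libraries, a 676-fold difference. The Y-linked genes did the reverse. Ddx3y stood at 55.1 ± 4.33 CPM in the STAT6-/- libraries and 0.08 ± 0.04 in WT, while Eif2s3y, Uty and Kdm5d had no counts in any WT library and were at least 331-fold, 147-fold and 173-fold higher in STAT6-/- against a floor of 3 counts per library. All 5 sex-linked genes passed edgeR's test (4 rose and Xist fell, adjusted over the list alone also 4 and 1). The list rose by camera (adjusted p = 6.26e-05; adjusted p = 0.417 with an estimated correlation), with a median log2 fold change of 11.9, or 7.43 with the 3 genes absent from WT at their bound. Every STAT6-/- library thus had the profile of a male and every WT library that of a female, so each difference below is between genotypes and between sexes at once. On the X chromosome 27.5% of 484 tested genes changed, 27 of them upward among 133, against 22.7% of 14518 autosomal genes (two-sided Fisher's exact test over genes, p = 0.0155; genes are not independent replicates).

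Of 15066 genes tested, 1718 were higher and 1731 lower in the STAT6-/- colons (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05), 22.9% in all. At least 2-fold changes numbered 988 up and 962 down. The 2 groups did not overlap in 46.6% of the genes, where chance gives 10%. The first principal component of log2 CPM held 61.4% of the variance and parted the genotypes, with scores of -85.6, -21.7 and -68.7 in STAT6-/- and 47.8, 60.9 and 67.3 in WT. STAT6-/- replicate 2 lay nearest to WT on this axis, and its Spearman correlation was 0.953 with WT replicate 1, 0.946 with STAT6-/- replicate 1 and 0.94 with STAT6-/- replicate 3. The WT libraries correlated with one another at 0.976 to 0.99 and the STAT6-/- libraries at 0.94 to 0.953. The counts depended on single libraries: without WT replicate 2 or WT replicate 3, 21 and 12 genes were higher and 10 and 6 lower, although 4372 and 4285 genes had an unadjusted p under 0.05 and 1812 and 1774 an adjusted p under 0.1. They were 656 and 751 without WT replicate 1, 1033 and 751 without STAT6-/- replicate 1 and 2750 and 2440 without STAT6-/- replicate 2, while DESeq2 gave 2713 and 2403 and a fit with the trends on GC content and length removed, added after seeing the data, gave 1045 and 992.

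Among the 10 largest rises, Eif2s3y and Ddx3y were Y-linked and the other 8 were not. Oas1a and Oas1g, neighbouring genes of 2'-5' oligoadenylate synthetases on chromosome 5 (120896256 to 120907544 and 120876142 to 120887613), were nearly absent from WT at 0.35 ± 0.558 and 0.323 ± 0.28 CPM and reached 352 ± 49.9 and 194 ± 29.6 CPM in STAT6-/-. The log2 fold changes of Oas1a and Oas1g were 9.99 and 9.23, ran from 9.40 to 13.27 and from 8.62 to 9.66 with 1 library left out, and were 7.36 and 6.42 with log2 FPKM plus 1. Oas1a lost its call without WT replicate 3 (edgeR adjusted p = 0.066). Pla2g2a, a secreted phospholipase that kills Gram-positive bacteria, rose 255-fold to 850 ± 562 CPM (log2 fold change 8.00 ± 0.82, edgeR adjusted p = 0.00873). Nos2, the inducible nitric oxide synthase, rose 200-fold to 565 ± 285 CPM (7.64 ± 0.84, adjusted p = 0.00965). Plet1, a membrane protein of epithelial progenitors, rose 198-fold to 964 ± 487 CPM (7.63 ± 0.92, adjusted p = 0.00965). The chloride channel accessory genes Clca4b and Clca3b rose 177-fold and 98.7-fold, and the lipid transporter Mfsd2a rose 89.5-fold. These 3 log2 fold changes were 7.46, 6.62 and 6.48, and with 1 library left out they ran from 6.80 to 9.21, from 6.14 to 7.63 and from 5.86 to 8.65, that of Nos2 from 7.19 to 8.46 and that of Plet1 from 7.21 to 8.86. Oas and Clca genes are families of close relatives, so that the division of reads among their members is uncertain.

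Among the 10 largest falls, Xist came first. Nxpe5 and Zan, which lie close together on chromosome 5 (138207499 to 138251876 and 137378637 to 137477064), were 47.5-fold and 29.3-fold lower, at 4.49 ± 2.14 and 1.14 ± 0.204 CPM in STAT6-/- against 213 ± 28.5 and 33.7 ± 7.72 in WT. Their log2 fold changes were -5.57 ± 0.42 and -4.87 ± 0.28 (edgeR adjusted p = 0.00302 and 0.00113). Spink5, an epithelial serine protease inhibitor, was 29.8-fold lower (log2 fold change -4.90 ± 1.22, edgeR adjusted p = 0.0318), with 88.48, 8.75 and 12.59 CPM in the WT libraries. The log2 fold change of Spink5 was -6.01 without STAT6-/- replicate 2 and -3.12 without WT replicate 1, and its call was lost without any single library but STAT6-/- replicate 2, with limma-voom, with log2 FPKM plus 1 and with GC and length trends removed. The fat cell genes Car3 and Cfd were 26.9-fold and 23.6-fold lower, with WT levels of 62.9 ± 73.0 and 57.6 ± 56.4 CPM that varied between libraries. The log2 fold changes of Car3 and Cfd were -4.75 and -4.56, without WT replicate 3 they were -3.16 and -3.38 and without STAT6-/- replicate 3 -6.38 and -6.90. Both calls were lost without STAT6-/- replicate 1 or any WT replicate, with no filter and with GC and length trends removed, and that of Car3 also with limma-voom. Cyp2e1 and Inmt, enzymes of small-molecule metabolism, were 21.5-fold and 18.6-fold lower. The log2 fold changes of Cyp2e1 and Inmt were -4.42 and -4.21, -3.42 and -3.19 without WT replicate 3 and -5.46 and -4.96 without STAT6-/- replicate 3, and both calls were lost without STAT6-/- replicate 1, WT replicate 2 or WT replicate 3. Fxyd4, a regulator of the sodium pump, fell from 151 ± 37.3 to 8.87 ± 10 CPM, and Dbp, a clock-controlled transcription factor, fell 16.6-fold. The log2 fold changes of Fxyd4 and Dbp were -4.09 and -4.05, and with 1 library left out they ran from -5.46 to -3.49 and from -4.71 to -3.63. That of Fxyd4 was -5.60 with limma-voom and -3.46 with GC and length trends removed. Fxyd4 had an edgeR adjusted p of 0.0636 without STAT6-/- replicate 2, 0.0883 without WT replicate 1, 0.0652 with no filter and 0.0786 with GC and length trends removed. Of the 21 genes named by size, Stat6 included, 14 lost their call without WT replicate 2 and 15 without WT replicate 3. The sex-linked genes, Oas1g, Nxpe5 and Zan kept theirs in both cases, and all 21 kept their direction.

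**Figure D1:**
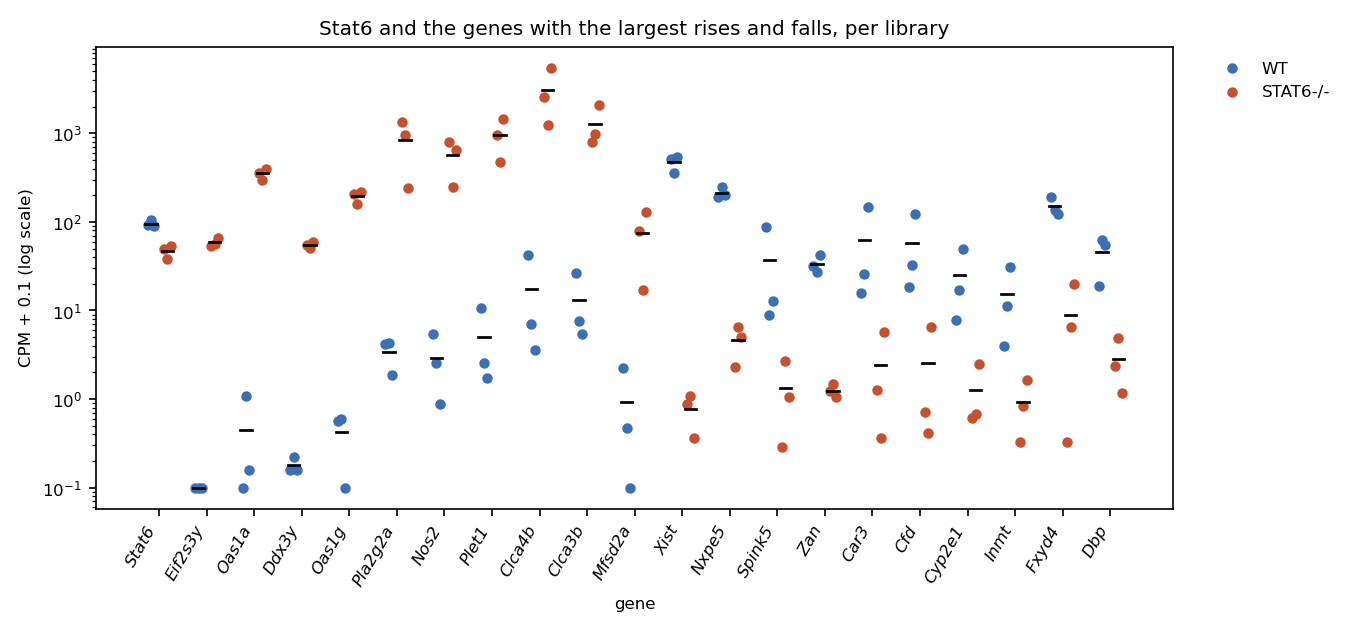
Expression of Stat6, the 10 genes with the largest rises and the 10 with the largest falls in each of the 6 libraries, in CPM plus 0.1 on a log axis. Points are libraries (3 WT and 3 STAT6-/-) and black bars are group means; the 2 groups do not overlap for any gene shown, and Stat6 keeps 49.8% of its WT level.

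Interferon-stimulated genes were higher in the STAT6-/- colons: 27 of 29 rose (29 adjusted over the list alone), with a median 6.59-fold difference (camera adjusted p = 9.84e-16; adjusted p = 0.696 with an estimated correlation). Besides Oas1g and Oas1a, the members with the smallest p were Stat2 and Zbp1. Stat2, a subunit of the interferon-activated transcription complex, stood at 254 ± 58.4 against 38.4 ± 8.46 CPM. Zbp1, a sensor of Z-form nucleic acid, stood at 279 ± 63.4 against 47.1 ± 15.5 CPM. Other members had larger folds, among them Oas2 (34.1-fold), Ifi44 (30.7-fold) and Ifit2 (26.8-fold). In STAT6-/- replicates 1, 2 and 3 Oas2 stood at 198, 77.3 and 219 CPM and Ifit2 at 757, 159 and 485. Oas1a stood there at 356, 300 and 400 CPM and Oas1g at 208, 161 and 215, with a smaller drop in replicate 2. Whether the near absence of Oas1a and Oas1g from WT reflects interferon or another difference between the mice was not tested. Irf7, the most abundant member, rose 3.38-fold. Antigen presentation and interferon-gamma genes moved the same way, with 21 of 30 rising (25 adjusted over the list alone) and a median 5.7-fold difference (camera adjusted p = 1.94e-14; adjusted p = 0.696 with an estimated correlation). MHC class II genes had the smallest p in that list. H2-DMb1 rose 10.2-fold, the invariant chain Cd74 11.8-fold to 1702 ± 220 CPM, H2-DMa 8.13-fold and H2-Ab1 7.07-fold, with edgeR adjusted p from 0.00113 to 0.00214. The class I gene H2-D1, the most abundant member, rose 3.97-fold, and class I genes share reads with their relatives. In the JAK-STAT family list 8 of 20 genes rose and Socs2 and Pias1 fell (9 and 2 adjusted over the list alone; camera adjusted p = 0.0162; adjusted p = 0.781 with an estimated correlation). Socs3 rose 16.7-fold, Jak3 6.19-fold and Socs1 8.29-fold, while Jak1, abundant in both groups, had a log2 fold change of -0.09 ± 0.20. The JAK-STAT list had a camera adjusted p of 0.0508 with GC and length trends removed and 0.113 without STAT6-/- replicate 3. Without WT replicate 2 and WT replicate 3, 5 and 1 interferon-stimulated genes and 7 and 5 antigen presentation genes passed the edgeR test.

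Epithelial defence genes rose as a list, with 9 of 25 higher (11 adjusted over the list alone; camera adjusted p = 0.00767; adjusted p = 0.696 with an estimated correlation). Beside Pla2g2a and Nos2, Ido1, which degrades tryptophan, rose 26.8-fold to 189 ± 80.1 CPM, and the NADPH oxidase Nox1 rose 10.4-fold to 35.3 ± 15.6 CPM. Lypd8, the most abundant member, stood at 15920 ± 3465 CPM against 23610 ± 3274 (edgeR adjusted p = 0.203). Of the acute inflammatory mediators 5 of 19 tested rose, Tnf, Lif, Ccl7, Il11 and Mmp10 (6 adjusted over the list alone), and the list rose (camera adjusted p = 0.00895; adjusted p = 0.781 with an estimated correlation). Tnf went from 1.96 ± 1.33 to 22.4 ± 1.35 CPM, an 11.4-fold rise. The other 16 members of that list, among them Ifng with 79 counts over the STAT6-/- libraries and 0 over WT, had too few counts to be tested. Leaving out STAT6-/- replicate 2 gave the defence list an adjusted p of 0.0543, and leaving out STAT6-/- replicate 1 or 3 gave the inflammatory list 0.0512 and 0.101.

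The T cell, macrophage, neutrophil and endothelial lists were called higher, each with few single genes past the threshold. In the T cell and innate lymphoid list 6 of 25 rose (11 adjusted over the list alone; camera adjusted p = 0.000713; adjusted p = 0.781 with an estimated correlation), led by the cytotoxic granule genes Gzmb (35.1-fold, to 8.54 ± 5.38 CPM) and Gzma (7.08-fold), the T cell kinase Zap70 and the T-bet gene Tbx21. In the macrophage and monocyte list Cd14, Ly6c2 and Itgax of 23 rose (2 adjusted over the list alone; camera adjusted p = 0.00682; adjusted p = 0.799 with an estimated correlation), Cd14 by 4.35-fold to 265 ± 25.8 CPM. The abundant macrophage gene Lyz2 stood at 423 ± 300.0 against 299 ± 103 CPM (edgeR adjusted p = 0.537). In the neutrophil list only Retnlg of 13 passed, and none adjusted over the list alone, with 5 at an unadjusted p under 0.05 by edgeR and 5 by DESeq2 (camera adjusted p = 0.0156; adjusted p = 0.781 with an estimated correlation). The endothelial list rose with Plvap, Vwf and Flt1 of 17 higher (6 adjusted over the list alone; camera adjusted p = 0.0156; adjusted p = 0.781 with an estimated correlation). Leaving out STAT6-/- replicate 3 ended the neutrophil (adjusted p = 0.176), macrophage (0.113) and endothelial (0.101) calls, leaving out STAT6-/- replicate 1 the neutrophil (0.0959) and macrophage (0.0585) calls, and leaving out WT replicate 1 the endothelial call (0.1).

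In the B cell and follicle list 1 of 22 genes rose, Ltb, a lymphotoxin subunit, and none adjusted over the list alone (8 at an unadjusted p under 0.05 by edgeR, 12 by DESeq2). The B cell list was not called (camera adjusted p = 0.0508), but was called in 7 of 18 other settings, DESeq2 among them (0.00218). Its STAT6-/- values were uneven, with Cd79a at 38.6 ± 41.7 CPM against 8.15 ± 1.66 in WT. Plasma cell genes rose as a list, 8 of 12 in number (8 adjusted over the list alone; camera adjusted p = 0.000277; adjusted p = 0.696 with an estimated correlation), with Derl3 5.3-fold higher and Irf4, the transcription factor of plasma cell differentiation, 3.2-fold higher. Edem2 and Xbp1, also members, act in the secretory pathway of many cell types. Jchain, the most abundant, stood at 1364 ± 257 against 846 ± 398 CPM (edgeR adjusted p = 0.191). In the eosinophil list 1 of 6 genes rose, the eotaxin receptor gene Ccr3 (1 adjusted over the list alone; camera adjusted p = 0.202), and in the mast cell list 1 of 10, the interleukin-33 receptor gene Il1rl1 (1 adjusted over the list alone; camera adjusted p = 0.524).

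Of the lists tied to type 2 immunity, camera called that of cytokines and receptors higher but did not call that of STAT6-inducible genes. Of 18 STAT6-inducible genes, 4 rose and 2 fell (5 and 2 adjusted over the list alone), and the list was not called (camera adjusted p = 0.323). The chemokine gene Ccl8 rose 9.71-fold, the interleukin-4 receptor gene Il4ra 4.61-fold and Socs1 8.29-fold. Retnlb, a goblet cell peptide, rose from 4.86 ± 4.66 to 113 ± 89.0 CPM, while Ccl24 fell 8.78-fold and Clca1, a secreted mucus protein and the most abundant member, fell from 10690 ± 812 to 1934 ± 1503 CPM (log2 fold change -2.47 ± 0.66, edgeR adjusted p = 0.0391). The call of Clca1 was lost with GC and length trends removed, without STAT6-/- replicate 1 and without any single WT replicate. Retnlb and Clca1 are also members of the goblet list. Of the type 2 cytokines and receptors 6 of 14 rose (8 adjusted over the list alone; camera adjusted p = 0.00682; adjusted p = 0.781 with an estimated correlation). Gata3, the transcription factor of type 2 lymphocytes, rose 6.15-fold, Il13 rose to 1.56 ± 0.916 from 0.04 ± 0.035 CPM and Il1rl1 rose 7.4-fold. Il13ra1, the most abundant member, had a log2 fold change of 0.24 ± 0.19. That list had an adjusted p of 0.0547 without STAT6-/- replicate 1.

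Goblet cell and mucus genes went both ways, with 6 of 22 higher and 2 lower (8 and 4 adjusted over the list alone; camera adjusted p = 0.24). The membrane mucin Muc4 rose 22.7-fold to 135 ± 65.1 CPM, Galnt12, which starts O-glycans, rose 1.89-fold and the transcription factor Creb3l1 rose 2.22-fold, while Ang4 and Clca1 fell. Muc13, the most abundant member, stood at 5545 ± 1285 against 3660 ± 890.0 CPM (edgeR adjusted p = 0.178). In the tuft cell list the interleukin-25 receptor gene Il17rb was among 2 of 14 that rose (2 adjusted over the list alone; camera adjusted p = 0.421). In the enteroendocrine list Gcg and Cck of 17 rose and Scgn, Insl5 and Cpe fell (2 and 3 adjusted over the list alone; camera adjusted p = 0.917), and its median of -0.25 and mean of 0.07 had opposite signs. Gcg, which encodes the glucagon-like peptides, rose 2.62-fold to 43.8 ± 5.67 CPM.

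The absorptive colonocyte list had a median log2 fold change of -0.02 and a mean of 0.21 over strong changes in both directions. Of 31 genes 6 rose and Car1, Abcg2 and Mep1a fell (7 and 9 adjusted over the list alone; camera adjusted p = 0.869). The carbonic anhydrase Car1 fell from 1675 ± 220 to 159 ± 59.4 CPM (log2 fold change -3.40 ± 0.33, edgeR adjusted p = 0.00732), and Clca4a and the water channel Aqp4 rose 10.5-fold and 14.4-fold. Krt8, the most abundant member, stood at 7206 ± 2103 against 4065 ± 673 CPM (adjusted p = 0.0861). In the stem cell and Wnt target list Ephb2 of 15 rose and Tnfrsf19, Nkd1 and Slc12a2 fell (1 and 3 adjusted over the list alone; camera adjusted p = 0.865, direction down, against a median of 0.18). In the tight junction list Cldn23, Dsc2, Tjp3 and Jup of 24 rose and Mylk, Myl9 and Ocln fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.593); Mylk and Myl9 are also smooth muscle genes. Of 14 small intestine genes, Ada, Slc5a1 and Alpi rose and Rbp2, Slc10a2, Enpep and Slc15a1 fell (3 and 4 adjusted over the list alone; camera adjusted p = 0.856, direction down, against a median of 0.06). In the list of Hox genes of the distal colon and hindgut, none of 13 changed by edgeR, none had an unadjusted p under 0.05 and DESeq2 called none (camera adjusted p = 0.588).

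Dividing-cell genes were higher in the STAT6-/- colons: 16 of 31 cell cycle genes rose (26 adjusted over the list alone), with a median 4.06-fold difference (camera adjusted p = 8.55e-09; adjusted p = 0.781 with an estimated correlation). The mitotic regulators Foxm1, Ube2c and Ccnb2 rose 8.63-fold, 7.65-fold and 6.15-fold, whereas Pcna, the most abundant member, had a log2 fold change of 0.26 ± 0.21. Cholesterol synthesis genes rose in 14 of 21 cases (19 adjusted over the list alone; camera adjusted p = 1.15e-08; adjusted p = 0.696 with an estimated correlation), with Mvd 5.41-fold, Fdps 3.89-fold and Mvk 2.9-fold higher. Hmgcs1, the most abundant, rose from 180 ± 39.3 to 409 ± 39.7 CPM. Of the unfolded protein response genes 9 of 23 rose (9 adjusted over the list alone; camera adjusted p = 0.000401; adjusted p = 0.696 with an estimated correlation), among them Syvn1, Sdf2l1, Sel1l and the chaperone Calr by 2.44-fold, 3.44-fold, 1.7-fold and 2.76-fold. Without WT replicate 2 or WT replicate 3 no member of these 3 lists passed edgeR's adjusted threshold, whereas all 3 lists kept their camera call.

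Smooth muscle genes were lower in the STAT6-/- colons: 12 of 23 fell (21 adjusted over the list alone), with a median 2.28-fold difference (camera adjusted p = 3.76e-08; adjusted p = 0.781 with an estimated correlation). Tagln, the most abundant, fell from 3052 ± 226 to 835 ± 324 CPM, Synpo2 5.82-fold, Lmod1 2.59-fold and Mylk 2.62-fold. Adipocyte genes also fell as a list, through Retn, Adipoq, Fabp4, Car3 and Cfd of 10 (5 adjusted over the list alone; camera adjusted p = 0.00895; adjusted p = 0.781 with an estimated correlation). Without WT replicate 2 or WT replicate 3, 0 smooth muscle and 0 adipocyte genes passed edgeR's adjusted threshold. Both lists kept their camera call there. In the fibroblast and matrix list Lum, Postn and Dpt of 24 fell (3 adjusted over the list alone; camera adjusted p = 0.0517, and below 0.05 in 9 of 18 other settings), and in the striated muscle list Actn3 and Ckm of 6 fell (2 adjusted over the list alone; camera adjusted p = 0.0947). The enteric neuron and glia list was called in the other direction, with L1cam, Gal, Nos1, Gfap and Ret of 23 higher and S100b lower (5 and 1 adjusted over the list alone; camera adjusted p = 0.0291; adjusted p = 0.804 with an estimated correlation), and leaving out STAT6-/- replicate 1, STAT6-/- replicate 3 or WT replicate 1 gave it 0.0629, 0.25 and 0.0711. The exocrine pancreas list was not tested, since it had 2 genes with enough counts, Clps and Cela1, and a list needed 4; neither gene passed, and their log2 fold changes were -1.12 ± 0.49 and -1.27 ± 0.79. The haemoglobin genes of the erythroid list varied widely in WT (Hbb-b1 451 ± 618 CPM), and none of 6 genes passed edgeR's adjusted test, with 2 at an unadjusted p under 0.05 and 1 by DESeq2 (camera adjusted p = 0.438).

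The remaining metabolic lists were not called by camera, although fatty acid oxidation, xenobiotic metabolism and oxidative phosphorylation were called lower in 6, 3 and 2 of 18 other settings. In the fatty acid oxidation and PPAR target list 6 of 23 fell and Acadl and Ucp2 rose (7 and 3 adjusted over the list alone; camera adjusted p = 0.0607), with Acaa2 3.72-fold and the lipid droplet gene Plin2 2.26-fold lower. In the xenobiotic and retinoid list 6 of 26 fell and Ces1g rose (6 and 1 adjusted over the list alone; camera adjusted p = 0.103), with Aldh1a1, a retinal dehydrogenase, 2.93-fold lower and Adh1, the most abundant, at 904 ± 891 against 3902 ± 563 CPM (edgeR adjusted p = 0.0631). In the oxidative phosphorylation list 8 of 30 fell and Uqcrc1 rose (9 and 1 adjusted over the list alone; camera adjusted p = 0.133). The p53 and apoptosis list had 2 genes higher and Trp53inp1, Ccng1 and Phlda3 lower of 20 (3 and 3 adjusted over the list alone; camera adjusted p = 0.983, direction up, against a median of -0.04), and the immediate early and heat shock list had Jun and Zfp36 higher and Dusp1 lower of 23 (2 and 1 adjusted over the list alone; camera adjusted p = 0.638).

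**Figure D2:**
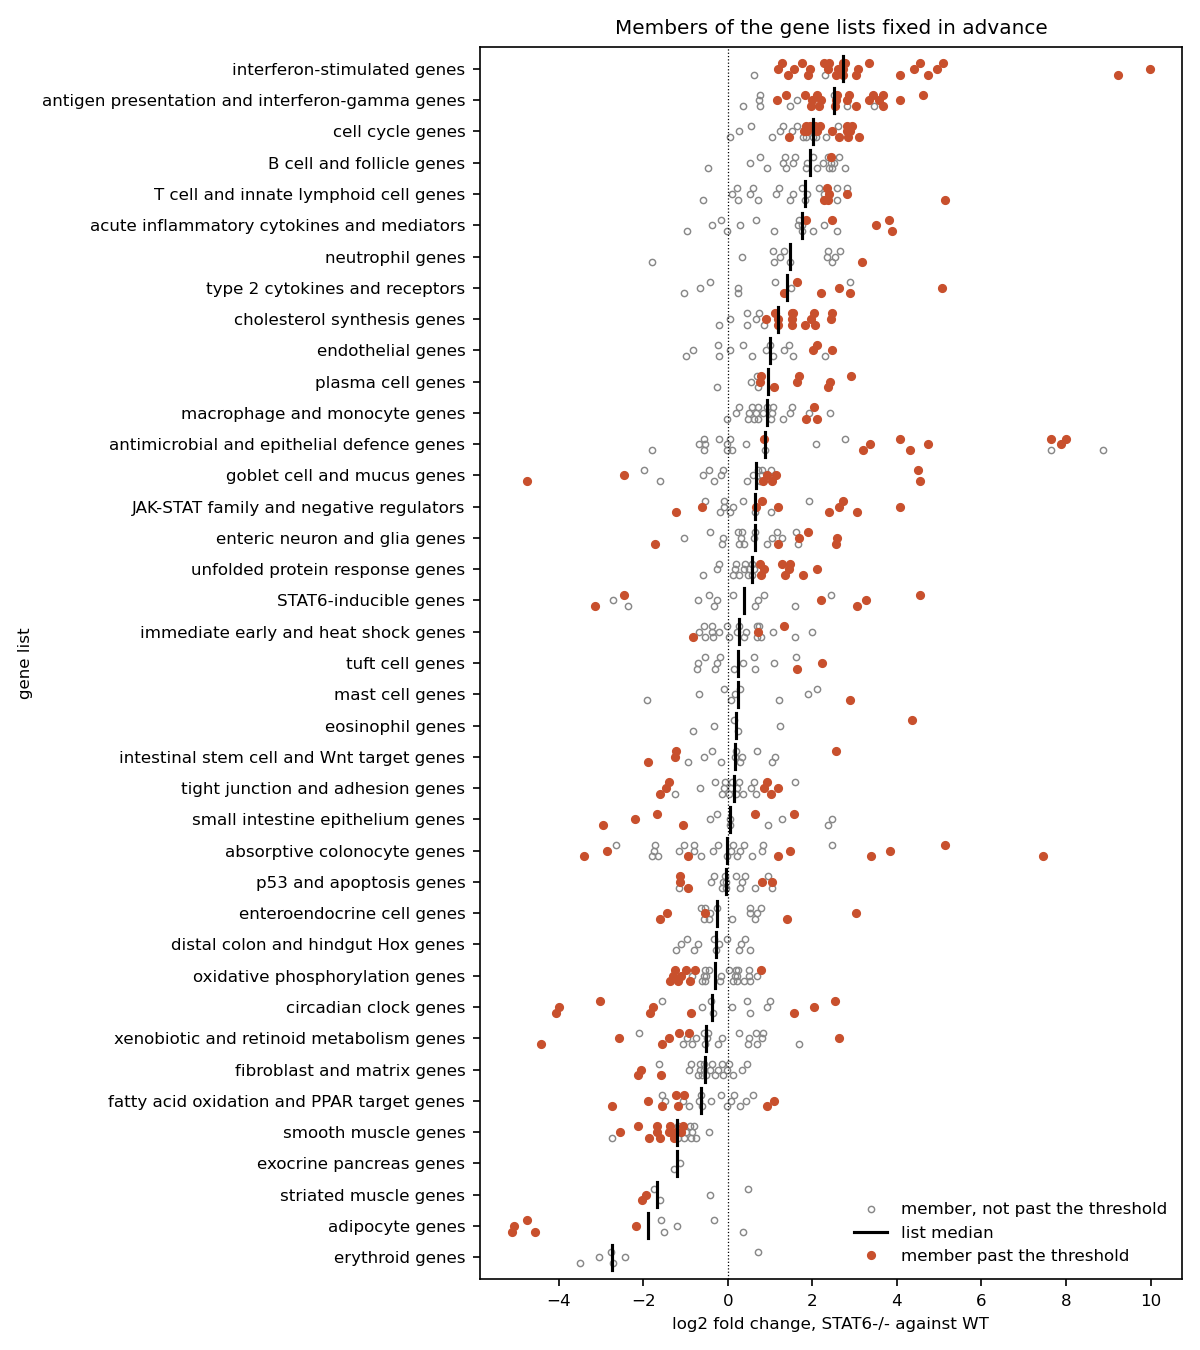
Log2 fold change between STAT6-/- and WT colons (horizontal axis) of each tested member of 39 gene lists, all but the sex-linked list. Filled points are genes past the adjusted threshold, open points the others, and black bars list medians, which run from -2.75 in the erythroid list to 2.72 in the interferon-stimulated list.

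Circadian clock genes changed in opposite directions, with 3 of 18 higher and 6 lower (4 and 7 adjusted over the list alone; camera adjusted p = 0.438). Cry1, a repressor of the clock, rose from 11.3 ± 2.13 to 65.7 ± 22.0 CPM (log2 fold change 2.54 ± 0.28, edgeR adjusted p = 0.00965). Nr1d1 and Nr1d2, which encode the REV-ERB repressors, fell from 138 ± 13.8 to 8.62 ± 6.21 CPM and from 92.8 ± 24.7 to 11.4 ± 6.84 CPM (-4 ± 0.53 and -3.02 ± 0.44, adjusted p = 0.0102 and 0.0115). Dbp fell from 45.2 ± 23.0 to 2.72 ± 1.91 CPM. Nfil3 and Usp2 rose 4.1-fold and 2.97-fold, and Tef, Per3 and Clock fell 3.61-fold, 3.42-fold and 1.81-fold. Bhlhe40, the most abundant member, had a log2 fold change of 0.45 ± 0.42. All 9 changed clock genes lost their edgeR call without WT replicate 2 or without WT replicate 3, where the log2 fold change of Dbp was -3.76 and -3.90.

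**Figure D3:**
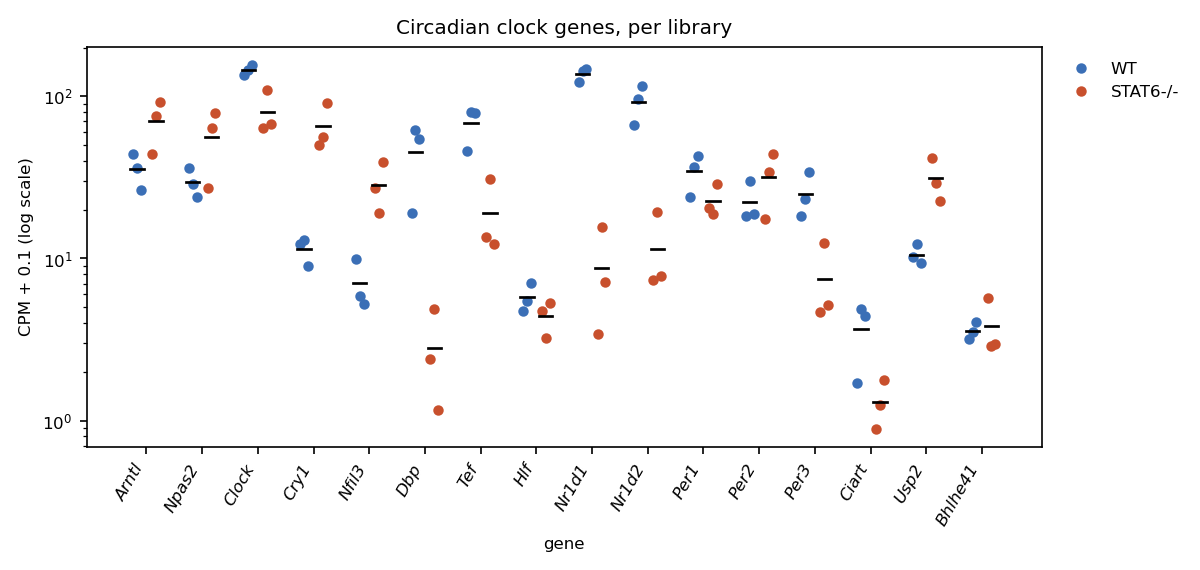
Expression of 16 clock genes in each of the 6 libraries, in CPM plus 0.1 on a log axis. Points are libraries and black bars group means. Nr1d1, Nr1d2, Dbp, Tef, Per3 and Clock are lower and Cry1, Nfil3 and Usp2 higher in all 3 STAT6-/- libraries than in all 3 WT libraries.

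Genes within 10 Mb of Stat6 were compared with the rest of the genome, since DNA beside a disrupted gene can come from the strain in which it was made. Of 118 tested genes in this window 26 changed, or 22.0%, against 22.9% elsewhere (odds ratio 0.952, two-sided Fisher's exact test over genes, p = 0.913). This comparison cannot show strain differences outside the window. Whether such differences, in either group of mice, underlie changes elsewhere was not tested. Pla2g2a on chromosome 4 is such a case, nearly absent from WT at 3.33 ± 1.36 CPM against 850 ± 562 in STAT6-/-.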

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

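The counts of changed genes depended most on single libraries. Genes higher in STAT6-/- ranged from 12 (without WT replicate 3) to 2750 (without STAT6-/- replicate 2), genes lower from 6 to 2440 and genes changed at least 2-fold from 18 to 3292 in the same fits; fewer libraries were tested in each. DESeq2 called 2713 higher, and the removal of GC and length trends left 1045 higher and 992 lower; the cause was not tested. With 1 library left out the Stat6 log2 fold change ranged from -1.059 (without WT replicate 3) to -0.851 (without STAT6-/- replicate 2), and was -0.939 without WT replicate 2; with GC and length trends removed it was -1.297. No named gene reversed under any setting. Other scalings and filters, limma-voom, FPKM and the removal of abundant genes kept the gene counts within 1.5 times.

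Lists higher in STAT6-/- were 0 with an estimated correlation, 7 by fry, and 10 (without STAT6-/- replicate 3) to 17 (without WT replicate 2) with 1 library left out. Lists lower were 0 with an estimated correlation, 0 by fry, 5 with no filter, 4 with either FPKM offset, 4 with the replicate block, 4 with GC and length trends removed, and 2 (without STAT6-/- replicate 1) to 5 (without STAT6-/- replicate 2) with 1 library left out; the cause was not tested. Robust estimation plays no part in the list test. The interferon, antigen presentation, cell cycle, cholesterol, T cell, plasma cell, unfolded protein response, smooth muscle, adipocyte and sex-linked lists were called by camera in every refit. Of these, fry did not call the cell cycle (fry adjusted p = 0.141), T cell (0.288), smooth muscle (0.0808) and adipocyte (0.141) lists. It called the others and the epithelial defence list. Lists that camera did not call were called in some of 18 other settings: fibroblast in 9, B cell in 7, fatty acid oxidation in 6, striated muscle and xenobiotic in 3 each and oxidative phosphorylation in 2. The neutrophil, endothelial and enteric neuron calls were also lost on FPKM, the neutrophil call with the strict filter (adjusted p = 0.0555), and the JAK-STAT call with GC and length trends removed (0.0508) or without STAT6-/- replicate 3 (0.113). With replicate number as a block, 1219 genes were higher and 1445 lower, and Spink5 (adjusted p = 0.0887) and Fxyd4 (0.0614) lost their calls; the numbers have no stated meaning, and not every sample correlates best with its own number. By Fisher's exact test the odds ratio near Stat6 ran from 0.758 to 1.22, and was 4.16 without WT replicate 2 (p = 0.221) and 0 without WT replicate 3 (p = 1), where few genes passed.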

Other observations

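Gene families outside the fixed lists were looked at after the results were seen. Cytosolic ribosomal protein genes, their close relatives included, were lower as a family in the STAT6-/- colons, with 65 of 82 falling, none rising and a median log2 fold change of -1.2; Rps4x fell from 1712 ± 183 to 530 ± 96.1 CPM (edgeR adjusted p = 0.00984). With GC and length trends removed the median was -0.79 and 50 of 81 fell. The count of falls was 40 without STAT6-/- replicate 1, 36 without WT replicate 1 and 0 without WT replicate 2 or WT replicate 3, with medians of -1.2, -1.24, -1.12 and -1.24. Schlafen genes, a family induced by interferon, rose in 7 of 8 cases with a median of 3.09, and Slfn4 rose 21.9-fold to 1773 ± 1118 CPM. Of 12 Ly6 genes 6 rose, among them Ly6a, 11.8-fold to 2306 ± 582 CPM, and of 7 apolipoprotein L genes 4 rose, with Apol9b 26.1-fold and Apol9a 17.4-fold higher. Of 8 chloride channel accessory genes 6 rose and Clca1 fell. Without WT replicate 2 or WT replicate 3, 0 Schlafen, Ly6 and chloride channel accessory genes passed, and 1 and 0 apolipoprotein L genes. The family medians there were 3 and 3.32 for Schlafen, 1.57 and 1.56 for Ly6 (1.67 with all libraries), 3.87 and 3.58 for chloride channel accessory (3.76) and 2.71 and 1.88 for apolipoprotein L genes (2.04). Members of these families resemble one another and share reads. Of 17 aminoacyl-tRNA synthetase genes 8 rose, Wars by 4.29-fold, and Lars fell; of 14 glycolysis genes Hk2 and 1 other rose and 1 fell, and Hk2 rose 8.42-fold to 786 ± 328 CPM. Of 38 proteasome subunit genes 6 rose and 1 fell. For the glycolysis and proteasome genes the share called lay below the 22.9% called over all tested genes. Without WT replicate 2 or WT replicate 3, 0 genes of these last 3 families passed, with medians of 0.68 and 0.61 for the synthetases (0.7 with all libraries), 0.32 and 0.18 for glycolysis (0.27) and 0.09 and 0 for the proteasome (0.08). Of 21 histone genes, linker histones included, edgeR called 0, with 1 at an unadjusted p under 0.05; DESeq2 called 1 higher, and over all other settings 0 to 3 rose and 0 to 4 fell. Of 12 inflammasome and Nod-like sensor genes, Nlrc5, Nlrx1 and Mefv rose, a share near the 22.9% called over all tested genes. None passed without WT replicate 2 or WT replicate 3, with medians of 0.65 and 0.61 (0.72 with all libraries). The median was 0.09 over the 8 genes left by the filter of 1 CPM in 3 libraries. It was -0.06 over 7 genes with either FPKM offset.

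All explanations below were chosen, and their predictions written, only after the results were seen.

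The rise of the interferon-stimulated list was set against 3 explanations. Less muscle and fat in the STAT6-/- pieces would raise all other cell types alike, but the interferon median lay 2.74 above the absorptive colonocyte median (95% bootstrap interval over genes 2.11 to 3.67). The endothelial, goblet, tuft and enteroendocrine medians were 0.99, 0.66, 0.25 and -0.25, so these cell types did not move alike. All lay below the interferon median of 2.72, so less muscle and fat alone does not account for the rise. With GC and length trends removed the median was 2.55 (2.38 to 3.26), so those trends do not account for it either. Sex cannot be told from genotype, since 0 libraries had the sex-linked profile of the other genotype. The rise could therefore follow from STAT6 loss, from sex or from another difference between the groups of mice or of libraries.

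The opposite changes of clock genes were set against a different time of collection. The Bmal1-side genes lay 2.55 above the E-box-side genes in median log2 fold change (95% bootstrap interval over genes 0.42 to 4.31), with medians of 1 for 5 genes and -1.55 for 11. Clock, Per2, Usp2 and Bhlhe41 went against their arm, and Cry2 and Bhlhe40 were put in neither. The arms were drawn up after the directions were seen, so this difference does not decide for another time of day. The labels give no times, and time of day, genotype and sex cannot be told apart here.

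The Stat6 reads in the STAT6-/- colons were set against tissue or reads of this series' WT mice in those libraries. Xist stood there at 0.1458% of its WT level (0.0485% to 0.282% over pairs of libraries) and Stat6 at 49.8% (37.0% to 59.9%), so a mixture with these mice, whose WT libraries are rich in Xist, does not account for them. Tissue of a male WT mouse, an intact allele in the STAT6-/- mice or a transcript still made from the disrupted gene could, and none of these was tested.

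The 6 libraries can be split into 3 and 3 in 10 ways. For genes called (3449) and genes changed at least 2-fold (1950), 1 of the 10 splits, the genotype split itself, gave a count as large, and the highest other count was 0. Every other split mixes the genotypes within its groups. The difference between genotypes then widens the spread within groups, so that few gene calls could arise there. For lists called by camera the genotype split gave 18, 4 of the 10 splits gave as many or more, and the highest other count was 20. A list count this large thus does not single out the genotype split. Every other split keeps part of the difference between genotypes, so these counts do not show how many lists would be called without it. With 10 splits no share under 0.1 is possible.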
